A study of Mus musculus with 4 samples.

How the data were processed

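Total RNA from the whole brain of male C57BL/6 mice aged 60 days was labelled with Cy3 and measured on custom 1-colour Agilent arrays for long noncoding RNA. There were 2 wild-type mice and 2 Mecp2 knockout littermates, and the labels describe each array as a separate mouse. All 4 arrays lay on 1 slide and carried the same scan stamp, so neither slide nor scan could be tested as a batch. Both knockout arrays lay side by side on the slide, as did both wild-type arrays, so position on the slide and genotype cannot be told apart.

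The intensity of each spot was deposited as the scanner software's processed signal, background-subtracted and spatially detrended with Agilent Feature Extraction 10.5.1.1, per the file headers. No scaling between arrays is recorded for those intensities, per the file headers. The value table the authors deposited holds log2 values for 30486 probes, and its scale is not stated in the labels. Set against the scanner files, each of its columns equals log2 of the processed signal, with signals under 5 set to 5, minus 1 constant per array. Between 90.1% and 98.8% of its probes lie within 0.001 of that constant, which lies close to the array's median. The column medians were 1.09 and 1.19 for wild-type replicates 1 and 2, and 1.04 and 1.1 for knockout replicates 1 and 2. The direction of the table is that of the signal, and its probes were not centred.

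The main values are log2 of the processed signal minus the 75th percentile of that quantity on the same array. Control spots and 20 negative-control probes were left out, spots marked as outliers by the scanner software were set to missing, and the spots of a probe were averaged. A probe was tested if it was well above background, by the software's own mark, on both arrays of at least 1 group. Of 40321 probes 27596 met that rule, and 27592 had values enough to fit. Genotype was the only term of a linear model in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all probes fitted, with a threshold of 0.05. A count at an unadjusted p under 0.05 with a fold of at least 1.5 was kept as a description. The number of arrays limits the precision, and an exact two-sided permutation test of 2 against 2 arrays cannot go below a p of 0.333.

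A probe that was not well above background on any array of a group has only a bound there. Its bound is the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of 2 values: the lowest signal of any probe marked well above background on that array, and the probe's own signal. Figures were drawn with matplotlib 3.10.9.

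Symbols came from a table of RefSeq genes of assembly GRCm38.p6, matched by accession without version. That table names 252 of 315 RefSeq noncoding probes and 58 of 60 RefSeq protein-coding probes, and 313 of all 40321 probes. The array was designed on the mm9 build, so no coordinates from the table are given. The transcript class was taken from the accession: NM and XM for protein-coding, NR and XR for noncoding, and no class for the rest. An NR accession can be a noncoding transcript of a gene that also encodes a protein, and the accession is then printed with the symbol. The files pair no gene name with cDNA accessions that start with AK or BC, with UCSC transcript identifiers or with ultraconserved elements.

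The genes to name were set before the data were examined, as were the 32 gene lists, the model and most alternatives. The rule names Mecp2 and the transcripts the study singled out. It then takes, per class, up to 7 probes higher and 7 lower past the threshold whose knockout values lie on 1 side of both wild-type values. Where too few pass, it fills up by the smallest unadjusted p among such probes with at least 1.5-fold. Of each list it names up to 4 members past the threshold, or else the 2 with the smallest p. Lists with at least 5 tested genes were tested with limma's camera at an inter-gene correlation of 0.01, with the brightest probe of each gene. Adjustment was by Benjamini-Hochberg over the lists tested, and the test was repeated with an estimated correlation.

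The method was tested on simulated data for 27420 probes of this comparison, with 50 probes given each fold. At the adjusted threshold it recovered 0 of 50 probes given 2-fold, 0 of 50 given 4-fold, 25 of 50 given 8-fold and 41 of 50 given 16-fold, with 2 false calls. At an unadjusted p under 0.05 it recovered 23, 49, 50 and 50 of them. The simulated noise was independent between arrays, with 1 variance per probe for both genotypes. In the data the median SD between arrays was 0.39 in wild type and 0.19 in knockout. Differences of replicate 1 from replicate 2 also correlated between genotypes, at 0.498 across probes. The recovered counts therefore hold for the simulated noise only.

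Alternatives set beforehand were centring each array on its median, quantile normalization, normexp background correction with an offset of 50, no filter on dim probes, and a filter that needs all 4 arrays above background. The others were keeping outlier spots, an intensity trend or a robust prior in the moderation, the authors' value table, leaving out each array in turn, and the replicate number as a block. The files hold no mean spot signal, so normexp used the median spot signal and the local background median. Cyclic loess, and normexp followed by quantile normalization, were added after the data were seen.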

Results

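Brain RNA of 2 wild-type and 2 Mecp2 knockout mice, males aged 60 days with the knockouts littermates of the wild types, was measured on arrays made mostly of long noncoding RNA probes. Each array held 41356 spots for 40321 probes. Of these, 33137 probes carried an AK cDNA accession, 5219 a UCSC transcript identifier, 962 an ultraconserved element, 329 a BC cDNA accession, 315 a RefSeq noncoding accession and 60 a RefSeq protein-coding accession. The median processed signal was 18.2 for wild-type replicate 1, 35.3 for wild-type replicate 2, 42.7 for knockout replicate 1 and 47.1 for knockout replicate 2. In the same order, 61.3%, 69.5%, 70.5% and 71.7% of probes were well above background, and 0 spots were saturated. Across tested probes, Pearson's r was 0.957 between the wild-type arrays and 0.984 between the knockout arrays, while pairs of unlike genotype gave 0.959 to 0.986. Probes are not independent replicates, so these values describe the arrays only. The median SD between arrays was 0.39 in wild type and 0.19 in knockout on the log2 scale. For 63 probes printed at 10 or more spots it was 0.45 and 0.14, against 0.08 to 0.09 between the spots of a probe within an array.

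Mecp2 encodes a protein that binds methylated DNA, and mice that lack it are a model of Rett syndrome. The comparison asks which brain transcripts, noncoding ones above all, differ in level without it. In these data the transcripts AK081227 and AK087060 were brighter in both knockout brains than in either wild-type brain, and the mRNA of Gamt, an enzyme of creatine synthesis, was dimmer. None of them passed the threshold adjusted over all probes. No probe on the array was named for Mecp2, so the genotype labels could not be checked by the targeted gene.

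AK081227 and AK087060 were singled out by the study from these same samples, so their values are not independent evidence. AK081227 lay at -2.92 and -2.90 in wild type and at -0.87 and -0.67 in knockout, in log2 units relative to the array's 75th percentile. Its knockout mean was 2.15 higher (SE 0.33), or 4.42-fold, and ranked number 6 of 27592 probes by limma's unadjusted p, 0.000377. The difference exceeded the SD between replicates, 0.01 in wild type and 0.14 in knockout. AK087060 had means of -3.88 in wild type and -2.05 in knockout, a difference of 1.82 (SE 0.36) or 3.54-fold, with limma's unadjusted p at 0.00139. It was well above background on 1 of 2 wild-type arrays and on both knockout arrays. Its direction turned under normexp, to -0.50, while that of AK081227 held but shrank to 0.10. For each the limma p adjusted over all probes was 0.9996. Adjusted over the list alone, 2 of 2 transcripts passed, which is not independent evidence. Gabrr2, a GABA receptor subunit gene listed with them beforehand, had no probe under that name.

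**Figure D1:**
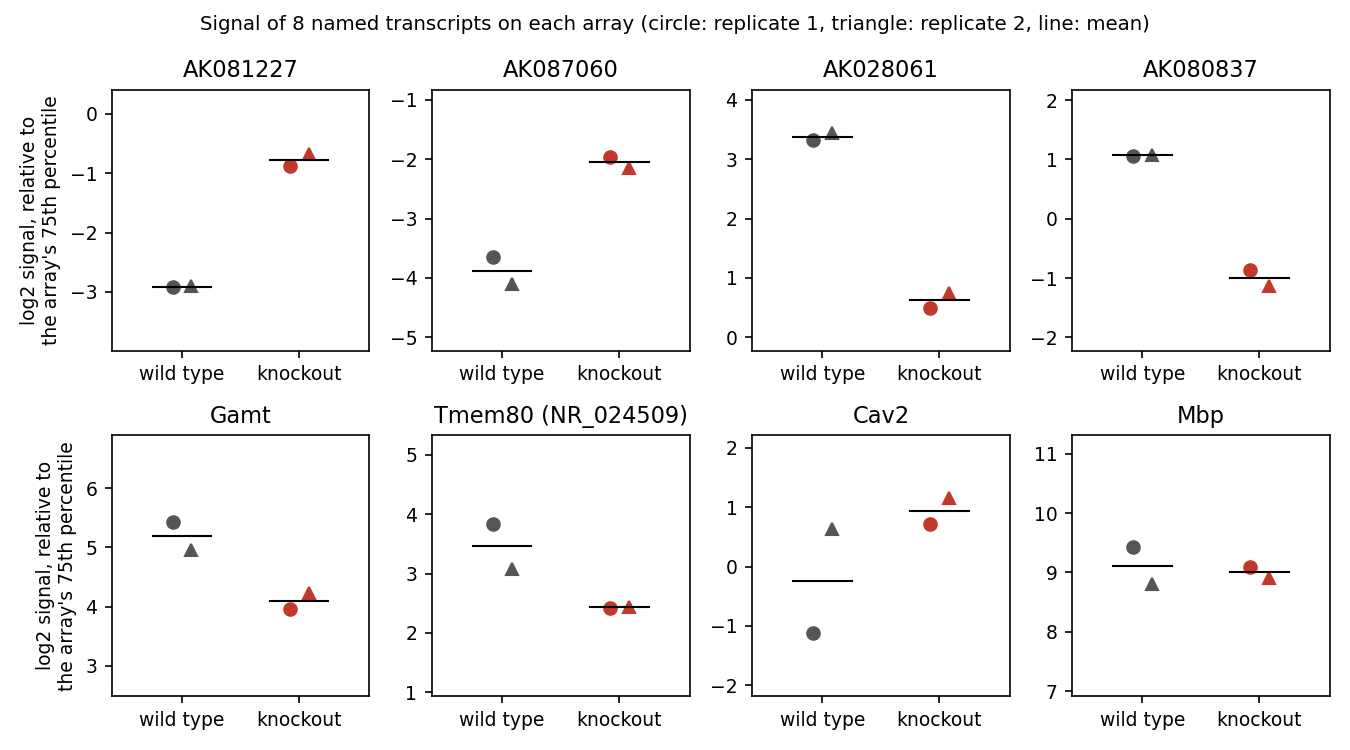
Log2 processed signal relative to each array's 75th percentile (vertical axes) for 8 transcripts in wild-type (grey) and knockout (red) brain, where each point is an array, circles are replicate 1, triangles are replicate 2 and the line is the mean. The knockout values of AK081227, -0.87 and -0.67, lie above both wild-type values, and those of Gamt lie below both, while the wild-type values of Cav2 lie far apart and the direction of Mbp turns with the scaling.

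Across the array, 0 of 27592 probes passed the adjusted threshold in limma, and the smallest adjusted p was 0.9996. After normexp, whose background fit gave the wild-type arrays a higher floor, 14751 passed. With the replicate number as a block 557 passed, though the labels do not say that the number marks a litter or batch. At an unadjusted p under 0.05 the main fit gave 860 probes, fewer than the 1380 that chance alone would give. All of them differed by at least 1.5-fold, because in that fit the moderated SE was too large for a smaller change to reach that p. Leaving out wild-type replicate 1 gave 2334 such probes and leaving out wild-type replicate 2 gave 5256, with the spread taken from the knockout pair alone. With an array of the knockout left out, 14 probes passed the adjusted threshold without replicate 1 and 32 without replicate 2, in fits that take the spread from the wild-type pair alone and assume the lone knockout array varies like it. Of the 860 probes, 640 were higher and 220 lower in knockout, or 74.4% higher. That split differed between scalings. The higher share was 56.1% of 933 probes after quantile normalization and 56.4% of 963 after cyclic loess. It was 42.0% of 1048 with arrays centred on their medians and 34.4% of 914 in the authors' table, which both move nearly every probe's change by 1 constant. It was 18.9% of 13464 probes after normexp, 56.9% of 311 after normexp and quantile normalization, 63.2% of 1031 with no filter and 56.3% of 526 among probes above background on all 4 arrays. The median change over all probes was -0.01 in the main scaling, -0.13 with arrays centred on their medians and -0.12 in the authors' table, so a change of about that size has no settled direction. Knockout values lay above both wild-type values for 4169 of 27420 probes and below both for 3973, together 29.7%, where chance gives 33.3%.

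By probe type, the 860 probes comprised 711 AK cDNAs (540 higher, 171 lower), 123 UCSC transcripts (79 higher, 44 lower), 9 ultraconserved elements (all 9 higher), 6 BC cDNAs (all 6 higher), 5 RefSeq noncoding transcripts (4 higher, 1 lower) and 1 RefSeq protein-coding gene, Gamt, which was lower. The other 5 carried other identifiers (2 higher, 3 lower). Among those tested, these were 9 of 362 ultraconserved elements, 6 of 258 BC cDNAs and 5 of 250 RefSeq noncoding transcripts. Each is a smaller share than the 860 of 27592 over all probes. These directions are those of the main scaling. RefSeq noncoding transcripts gave 3 higher and 5 lower with arrays centred on their medians, and 0 higher and 5 lower in the authors' table. Directions of the ultraconserved and BC probes were not counted under other scalings. The files do not pair AK accessions with gene names, and the 4 given here beyond the study's own were chosen after their values were seen, by smallest p. AK028061 had the smallest p of all, 8.58e-05 in limma before adjustment, with means of 3.38 in wild type and 0.62 in knockout, a difference of -2.75 (SE 0.34) or 6.74-fold. AK080837 was also lower in knockout, with a difference of -2.07 (SE 0.34, 4.19-fold, unadjusted limma p 0.000503). AK148638 was not well above background in wild type, where its mean was -5.07, and lay at -1.80 in knockout, at least 5.17-fold higher. AK034789 likewise had a mean of -5.53 in wild type, not well above background, and -2.91 in knockout, at least 2.40-fold higher. All 4 had a limma adjusted p of 0.9996. AK148638 passed the adjusted threshold with knockout replicate 1 left out (limma adjusted p 0.0456) and with knockout replicate 2 left out (0.024), under that same assumption about the lone knockout array. Both higher ones turned direction under normexp, to -0.37 for AK148638 and -0.73 for AK034789.

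**Figure D2:**
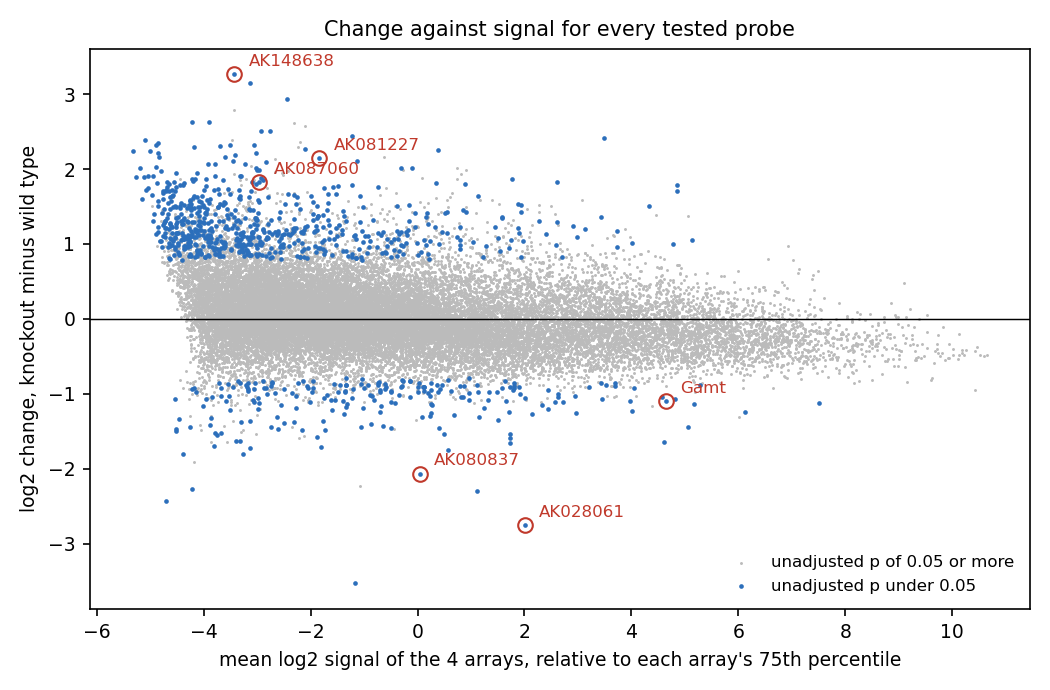
Log2 change, knockout minus wild type (vertical axis), against the mean log2 signal of the 4 arrays relative to each array's 75th percentile (horizontal axis), with a point per tested probe. The 860 probes at an unadjusted p under 0.05 are blue, and 640 of them lie above 0, many at the dim end; the circled probes are 5 AK accessions named in the text and Gamt, and none passes the adjusted threshold.

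RefSeq noncoding RNAs gave 0 of 250 probes past the threshold in limma, whether adjusted over all probes or over the class alone (smallest adjusted p 0.363), and 5 at an unadjusted p under 0.05. After normexp 132 passed. Knockout values lay above both wild-type values for 34 of these transcripts and below both for 32. Slc13a2os, an RNA antisense to a carboxylate transporter gene, the U7 small nuclear RNA gene Rnu7 and the long noncoding RNA 4932435O22Rik were higher in knockout but not well above background in wild type. Slc13a2os had means of -6.06 in wild type and -4.17 in knockout (unadjusted limma p 0.00145), too close to background for a fold. Rnu7 was at least 1.28-fold higher, with means of -4.73 and -3.64, and 4932435O22Rik at least 1.27-fold higher, with means of -4.68 and -3.82. Under normexp all of these turned direction. The pseudogene Ppp1r2-ps3 was 2.14-fold higher (log2 SE 0.47), and on the log2 scale NR_003546 was 0.85 higher (SE 0.36), a noncoding transcript of Lrrc57 (NR_027510) was 1.03 higher (SE 0.47) and NR_027465 was 0.82 higher (SE 0.36). Without wild-type replicate 1 the log2 differences for Ppp1r2-ps3 and Lrrc57 came to 0.49 each, and that for NR_027465 to 0.53.

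Among noncoding transcripts lower in knockout, NR_024509 of Tmem80 stood at 3.46 in wild type and 2.43 in knockout, a difference of -1.03 (SE 0.39, unadjusted limma p 0.0328). NR_027509 of Suv39h2, a histone methyltransferase gene, differed by -0.84 (SE 0.37) and the long noncoding RNA AA543186 by -0.83 (SE 0.39). NR_027359 and NR_027360 differed by -0.75 and -0.74, Gm14379 by -0.64 and Abhd11os by -0.83 (SE 0.49). Without wild-type replicate 1 the difference for Abhd11os was -0.18, for NR_027360 -0.36, for Gm14379 -0.37, for NR_027359 -0.47 and for Tmem80 -0.65, and without knockout replicate 1 that for AA543186 was -0.47. All 7 kept their direction in 16 of 16 alternatives, and all missed the main adjusted threshold, with unadjusted p from 0.0328 to 0.133 in limma. They were chosen for knockout values below both wild-type values, so leaving out an array could not turn them. Dropping the filter, changing the variance model and adding the block leave the estimate unchanged, so those could not turn it either.

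Probes with a protein-coding RefSeq accession were few. Of 59 tested, 0 passed the threshold in limma over all probes or over the class alone (smallest adjusted p 0.955), and 30 passed after normexp. At an unadjusted p under 0.05 there was 1, where chance alone would give 2.95. That gene was Gamt, at 5.43 and 4.95 in wild type and 3.96 and 4.23 in knockout, a difference of -1.10 (SE 0.36, 2.14-fold, unadjusted limma p 0.0191). It ranked number 334 of 27592 probes by that p. Gamt was also the only gene with a named probe from a list of 37 that earlier work tied to loss of Mecp2. Adjusted over the list alone its p stayed 0.0191 in limma, since adjusting over 1 gene changes nothing. Its direction held in 15 of 15 alternatives, from -1.33 to -0.40. Leaving out an array could not turn it, since both knockout values lay below both wild-type values. Changing the filter or the variance model and adding the block leave the estimate unchanged, so those could not turn it either. The caveolin gene Cav2 was 1.18 higher (SE 0.59), the glutathione transferase gene Gsta4 0.95 higher (SE 0.54), the histocompatibility gene H2-Q7 0.83 higher (SE 0.48) and the endosomal GTPase gene Rab5a 0.72 higher (SE 0.40). Wild-type replicate 1 carried most of those differences, since without it they came to 0.30, 0.17, 0.18 and 0.33. The fatty acid receptor gene Ppara was 0.87 higher (SE 0.46), or 0.28 without wild-type replicate 2, and Spats1 was 0.62 higher (SE 0.34). Both turned direction under normexp, to -0.40 and -0.20.

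Of the 32 gene lists, 24 had no gene with a named probe, and 5 had 1 such gene. Since most probes carry no gene name, these genes are not shown to be absent from the array. The 24 lists are, besides Mecp2 itself, those for GABA synthesis and interneurons, glutamate receptors, immediate early genes, glucocorticoid response, monoamines, cholesterol synthesis, the respiratory chain, the clock, synaptic vesicles, the postsynaptic density, and markers of neurons, astrocytes, microglia, vessels, choroid plexus, ependyma, meninges, blood, pituitary, cerebellum, striatum, olfactory bulb and thalamus. From other lists, the GABA receptor gene Gabrg1 differed by -0.03 on the log2 scale (SE 0.40), the ribosomal protein gene Rpl13a by -0.20 (SE 0.34), the myelin gene Mbp by -0.11 (SE 0.38) and the chaperone gene Hsp90ab1 by 0.66 (SE 0.50). Without wild-type replicate 1 the difference was -0.03 for Hsp90ab1, -0.08 for Rpl13a, 0.38 for Gabrg1 and 0.20 for Mbp. Without wild-type replicate 2 it was 1.36 for Hsp90ab1, -0.33 for Rpl13a, -0.44 for Gabrg1 and -0.43 for Mbp. Quantile normalization turned Gabrg1 to 0.07 and Mbp to 0.17, and normexp turned Rpl13a to 0.55.

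Only the lists of named long noncoding RNAs and of imprinted genes were large enough to test. Meg3, Peg13, Gnasas1 and Airn were tested in both, so the results of these lists are not independent. Every tested imprinted gene was measured at a noncoding accession. The 19 named long noncoding RNAs had a median change of 0.09 and a mean of 0.05, with a camera adjusted p of 0.71, and 12 of their 21 probes were higher and 9 lower. The list's median was -0.03 with arrays centred on their medians, 0.24 without wild-type replicate 1, -0.12 without wild-type replicate 2 and -0.01 without knockout replicate 1. The 5 imprinted genes had a median of -0.12 and a mean of -0.13 with a camera adjusted p of 0.71, and quantile normalization turned the median to 0.06. Their median was 0.02 without wild-type replicate 1, -0.41 without wild-type replicate 2, -0.06 without knockout replicate 1 and -0.02 without knockout replicate 2. With an estimated correlation both adjusted p were 0.725, and no member of either list passed the threshold, over all probes or adjusted over the list alone. Meg3 differed by -0.26 (SE 0.36), Gnas (NR_003258) by -0.20, Peg13 by -0.12, Gnasas1 by -0.09 and Airn by 0.03, and Kcnq1ot1 was not well above background in either group. The directions of Meg3 and Gnas turned under quantile normalization, cyclic loess and normexp. Meg3 came to -0.06 without knockout replicate 1 and -0.45 without knockout replicate 2. Without wild-type replicate 1, Gnas turned to 0.02, Peg13 to 0.31, Gnasas1 to 0.24 and Airn to -0.43. Dlx6os1, transcribed across a homeobox gene cluster of interneuron precursors, differed by -0.65 (SE 0.40) and kept that direction in 16 of 16 alternatives. Its knockout values lay below both wild-type values, so leaving out an array could only shrink or raise the difference. Changing the filter or the variance model and adding the block left the difference unchanged. Without wild-type replicate 1 it came to -0.23. Neat1 was 0.59 higher, Snhg1 0.51, Norad 0.38 and Malat1 0.32, and Miat differed by -0.55 and Dlx1as by -0.42, all short of the threshold. Neat1 came to 0.17 and Dlx1as to -0.21 without wild-type replicate 1, and Miat to -0.10 without wild-type replicate 2. The 2 probes of Tug1 disagreed, at 0.48 and -0.32, and without wild-type replicate 1 the first came to 0.07. The second came to -0.16 without knockout replicate 1 and -0.48 without knockout replicate 2. Xist, expected to be silent in males, was not well above background in wild type at NR_001463 but was so marked on both knockout arrays. Its means there were -5.19 and -4.36, with no fold to give. At NR_001570 it was well above background on 1 of 2 wild-type arrays and on both knockout arrays. There it differed by 0.09, or by -0.29 without wild-type replicate 1. Tsix was not well above background in either group.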

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

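The comparison of negative-control probes between genotypes was chosen after the share of them above background was seen. The array carries 20 negative-control probes at 800 spots, entered in the files as ordinary probes and used in none of the comparisons. They drew attention because a signal appeared in spots meant to stay dark, more often on the knockout arrays. On knockout replicate 1, 21.1% of those spots were well above background, and on knockout replicate 2, 19.3%. Wild-type replicate 1 had 9.63% and wild-type replicate 2 had 15.4%. A majority of spots was above background for 5 of the 20 probes in knockout and for 3 in wild type. The order of genotypes turned with the scaling: the median change, knockout minus wild type, was 0.48 (SD 0.29 over probes) before scaling and -0.25 (SD 0.29) after each array's 75th percentile was subtracted. The knockout arrays were also the brighter ones, with median processed signals of 42.7 and 47.1 against 18.2 and 35.3. No biological explanation was tested, and none of the named transcripts rests on these spots.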

How the results depend on the processing

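Cyclic loess, normexp followed by quantile normalization, and the test of a shared litter or preparation were chosen after results were seen. Slide and scan as a block were not run, since all 4 arrays share both, and nothing was run for Mecp2, for which no probe is named. The authors' table gave no value for protein-coding genes, and the filter on all 4 arrays left too few imprinted genes to test.

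The count of 0 probes past the adjusted threshold held under the other scalings, filters and variance models. Normexp gave 14751, with 132 noncoding and 30 protein-coding probes. Leaving out each replicate gave 0 to 32. The count of 860 probes at an unadjusted p under 0.05 with 1.5-fold became 13464 under normexp, 526 with the filter on all 4 arrays, where fewer dim probes were tested, 311 with normexp then quantile normalization, and 638 to 5256 with a replicate left out. Of the tested lists, 1 passed under normexp and 1 under normexp then quantile normalization (named long noncoding RNAs, adjusted p 0.000569 and 0.0251, against 0.265 to 0.952 elsewhere). After normexp the 1st percentile of log2 signal was 7.08 and 7.85 in wild type but 6.33 and 6.23 in knockout, so its background fit lifted dim wild-type signals, and the median change became -0.38.

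Directions reversed as follows; beyond normexp the cause was not tested. Normexp gave Slc13a2os -1.15, Rnu7 -1.11, 4932435O22Rik -1.03, Ppara -0.403, Spats1 -0.198, AK087060 -0.496, AK148638 -0.368, AK034789 -0.727, Xist -1.11, Gabrg1 0.663, Rpl13a 0.547, Meg3 0.541, Gnas 0.474, Mbp 0.763, and imprinted genes relative to other probes 0.474 (-0.169 in the main scaling). Quantile normalization gave Gabrg1 0.072, Meg3 0.0605, Gnas 0.0839, Mbp 0.173 and imprinted genes 0.0262. Cyclic loess gave Gabrg1 0.0989, Meg3 0.0256, Gnas 0.124 and Mbp 0.221. Normexp then quantile normalization gave Gabrg1 0.122, Rpl13a 0.00715, Meg3 0.1, Gnas 0.0244, Mbp 0.287 and imprinted genes 0.0566. With a replicate left out, Gabrg1 ran from -0.44 to 0.383, Hsp90ab1 from -0.0331 to 1.36, Gnas from -0.426 to 0.0243, Mbp from -0.429 to 0.204 and named long noncoding RNAs relative to other probes from -0.0482 to 0.0895. All 35 named values kept direction and side of the threshold with median centring, no filter, outlier spots kept, and either variance model. AK081227 ran from 0.0973 to 2.25 and AK028061 from -2.88 to -1.79, in the same direction in 16 of 16 alternatives. For both, the knockout values lay on 1 side of the wild-type values, so leaving out an array could not turn them. Changing the filter or the variance model and adding the block leave both estimates unchanged. The adjusted p of AK148638 was 0.0456 without knockout replicate 1, 0.024 without knockout replicate 2, 0.147 without wild-type replicate 2 and 0.555 without wild-type replicate 1, and over all its alternatives ran from 7.56e-14 under the block to above 0.99. Signal over background limits the dim probes, since 88.8% of tested probes were above background on wild-type replicate 1 against 99.6% on knockout replicate 2.

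With the replicate number as a block, 557 probes passed the adjusted threshold (485 higher, 72 lower), 2 of them noncoding and 1 protein-coding, and 2660 reached an unadjusted p under 0.05 with 1.5-fold. Of the 35 named values 7 passed under the block: AK081227, AK087060, AK028061, AK080837, AK148638, AK034789 and Slc13a2os. The block moved none of the other named values past the threshold, and no gene list. The labels do not say that the number marks a litter or batch, and there are only 2 pairs. Differences of replicate 1 from replicate 2 correlated between genotypes at 0.498 across probes, which are not independent replicates. A brightness trend was not the source, since the value was 0.502 after cyclic loess, nor dim probes, since it was 0.553 over the 9199 brightest probes. Local flaws were not the source for the 63 probes whose 10 or more spots spread over the array, which gave 0.773. Probes with fewer spots were not tested for local flaws, so that cause stays open for them. A shared litter or preparation could underlie the 0.498 and stays open. Position on the slide stays open too, since replicate 1 lay on the same side of replicate 2 in both genotypes.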

Other observations

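Chosen after the result was seen were the tests of array scaling and of Mecp2 genotype for the share of higher probes, the count of splits of the arrays, and cyclic loess. The tests of dim probes, of wild-type replicate 1 and of the probe groups were written beforehand.

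In the main scaling, more probes were higher than lower in knockout among those at an unadjusted p under 0.05, a share of 0.744. No test excluded an explanation. Without wild-type replicate 1, the dimmest array, the share was 0.679. A share of 0.60 or more had been set as the level that would exclude that array as the source, but the level was wrong. Leaving the array out moved the median change of all probes from -0.01 to 0.08, which by itself raises the share, and the spread then came from the knockout pair alone. Scaling between arrays stays open, since the share was 0.561 after quantile normalization, between the 0.55 set for that explanation and the share in the main scaling. Centring each array on its median adds 1 constant to every probe's change, and 42.0% of probes were then higher. The direction of the split thus depends on that constant. Which constant is right cannot be told from the share. Dim probes near background stay open too: among probes above background on all 4 arrays the share was 0.563, between 0.55 and 0.60. There 296 were higher and 230 lower, against 640 and 220 in the main fit, so only the higher ones fell. With no filter 652 were higher and 379 lower. The main rule admits a probe through either group. Of tested probes, 88.8% were above background on wild-type replicate 1, against 99.5% and 99.6% on the knockout arrays. Mecp2 genotype stays open as well. Its arrays hold their own part of the slide, so genotype and slide position cannot be told apart.

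The 4 arrays can be split into pairs in 3 ways, too few for a share under 0.05. The real split gave 860 probes at an unadjusted p under 0.05, and the highest other gave 3761, so 2 of the 3 splits gave as many. That highest one sets both arrays numbered 1 against both numbered 2, and its count points to a structure other than genotype. Whether that structure lies in the samples or in the arrays cannot be told. In both genotypes replicate 1 lay on the same side of replicate 2 on the slide and had the lower median processed signal. The last split gave 163, and the adjusted threshold was passed by 0 probes in all 3.

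Some protein-coding genes differed widely between the wild-type arrays and others little. Each array is a separate mouse, so mouse and array cannot be told apart. Replicate 1 minus replicate 2 was -1.81 for Tbp, -1.57 for Nono, -1.40 for Hsp90ab1 and -3.32 for Lhfp, on the log2 scale after scaling. In the other direction it was 1.19 for Ppia, 1.04 for Apoe, 0.98 for Gapdh and 1.73 for the proneural gene Ascl1. It was smaller for Rpl13a (0.25), Gk (-0.23) and Tfrc (0.45). Within the knockout pair the differences were -0.43 for Tbp, -0.26 for Nono, -0.15 for Hsp90ab1, -0.66 for Lhfp, 0.16 for Ppia, 0.25 for Apoe, 0.21 for Gapdh and 0.61 for Ascl1. They were 0.12 for Rpl13a, 0.15 for Tfrc and 0.11 for Gk, whose sign was opposite in wild type. The sign was the same in both pairs for 49 of 59 protein-coding probes (83.1%), against 69.8% of all tested probes. These genes were picked after their values were seen.

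Probes for ultraconserved elements covered 481 elements on both strands. For 46 elements both strands were above background on all 4 arrays, for 196 only 1 strand was, and for 239 neither. The hypothesis that these probes shift with genotype was tested with camera, as were RefSeq transcripts of pseudogenes and RefSeq long noncoding and antisense RNAs. Among 358 ultraconserved probes 202 were higher and 156 lower in knockout, with a median of 0.07 against -0.01 for all others, and the camera adjusted p over 3 groups was 0.507. Relative to the other probes that median was 0.08 with arrays centred on their medians, but 0.00052 after quantile normalization, -0.0046 after cyclic loess and 0.14 without wild-type replicate 1. It was 0.05 among probes above background on all 4 arrays. Pseudogene transcripts gave 44 higher and 38 lower of 82, with an adjusted p of 0.957. Long noncoding and antisense RNAs gave 36 higher and 40 lower of 76, also with 0.957. The median change was 0.02 for the pseudogenes and -0.06 for the long noncoding and antisense RNAs, against -0.00487 and -0.00474 for the other probes. Without wild-type replicate 1 the medians relative to the other probes were 0.09 and 0.02. With an estimated correlation all 3 adjusted p were 0.988. A p above the threshold had been set beforehand as evidence against a shift, but that level was wrong for so few arrays. With a correlation of 0.01 between probes, the 95% interval of the mean shift relative to other probes ran from -0.01 to 0.19 for ultraconserved probes, from -0.14 to 0.12 for pseudogenes and from -0.14 to 0.13 for long noncoding and antisense RNAs. The intervals rest on that preset correlation, while the adjusted p for ultraconserved probes moved from 0.507 to 0.988 with the estimated one. Shifts within the intervals stay open, and shifts beyond them are not excluded.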
